A study of Homo sapiens with 8 samples.

How the data were processed

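Total RNA was sequenced from undifferentiated H9 human embryonic stem cells, 4 WT and 4 EXT1-/- samples, with 3 technical replicates stated for each sample. Per the labels the cells grew feeder-free in E8 medium on vitronectin and were taken at passages 5 to 10. They were split with EDTA (1 mM), and the kinase inhibitor Y-27632 (5 µM) was present on the day of each split. RNA was isolated with TRIzol and Direct-zol columns, and libraries were made with a TruSeq Stranded Total RNA kit. The submitters' processing notes name the genome build GRCh38.p10, the aligner STAR, the quantifier RSEM and edgeR, without versions, roles or order. The annotation release, the strand setting and any read filter are not stated.

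The deposited table has 1 value per gene and sample for 15886 genes. It does not show whether the technical replicates were joined or 1 of them was kept. Its column names start with NPC, whose meaning is not stated, and also hold the word UNDIFF, while the sample labels say undifferentiated. The authors' values per sample are a score, here called the scaled read count: whole numbers, but not raw counts. The low values of each column lay on a ladder of evenly spaced steps (99.2% to 100% of values up to 400), as counts times a factor per sample and rounding give. The factors inferred from these ladders were 0.934 to 1.09, and the totals divided by them were 36.0 to 39.8 M counts. The deposited table also holds the authors' likelihood ratio score, their fold change and mean level in log2 units, and their p-value with its adjusted form, per the file headers. The lowest sum of a gene over the 8 samples was 109, so genes with lower sums had already been left out. Gene positions, strands and biotypes came from GENCODE release 29, which held 15854 of the 15886 identifiers, and 32 had no match.

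The plan fixed before the data were examined named a test for raw counts and, for normalized values, limma with a trend on log2 of the value plus a pseudocount. The latter was used, because the values were not raw counts. The tests that need raw counts (the quasi-likelihood and likelihood ratio tests of edgeR, DESeq2 and voom) were not used. Genes were kept when their counts per total (CPM) were at least those of 10 counts in the median library in at least 4 samples, which left 15868. The pseudocount was 0.5. The values were not scaled again, because the authors had scaled them. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 passed. Adjusted p-values in the text come from limma unless a sentence names another test. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

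In total 30 gene lists and 6 marker sets were fixed before the data were examined, and 34 of them had at least 4 tested members. Each was tested with camera in limma, which compares the members with all other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 34. Among the 6 lists that passed, the FGF and ERK response list also passed with an estimated correlation. The alternative fry tests whether members move, on balance, in 1 direction, without comparing them with other genes. The 22 autosomes were tested as sets in the same way. EXT1 was left out of the set test of its own list. Symbols are those of the deposited table, so CTGF stands for CCN2, ALPPL2 for ALPG and TMEM2 for CEMIP2.

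The genes named were fixed by rule before the data were examined. EXT1 and EXT2 came first. Next came the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those past the test, with at least a 2-fold change, no overlap between the groups, and a mean of at least 2 CPM in the higher group. In each list, the 4 tested members with the smallest adjusted p were named, whether or not they passed. Some genes fell under several parts of the rule, and it covers 160 different genes. Some genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen. Of the 15868 genes, 152 met the limits for the largest changes, 52 higher and 100 lower.

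Alternatives planned before the data were examined were size factors by the median ratio (RLE), no filter, a filter of 1 CPM, pseudocounts of 0.1 and 1, and replicate number as a block. Others were an adjusted p under 0.01, fry, an estimated correlation, and leaving out each library in turn. A term for the 2 library sets (alone or with an estimated correlation), the low mitochondrial set alone, and the treat test of limma against a fold of 1.2 were chosen after seeing the data. Shared sequence was measured as the share of the 31-mers of a gene's models that occur in another gene.

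The test was checked on simulated data with the same library sets, in which 50 genes were changed at each fold. The changed genes were drawn from those with a mean of at least 50 scaled counts. It recovered 16% of genes changed 1.25-fold, 62% at 1.5-fold, 84% at 2-fold and 100% at 4-fold, and 0.8% of its calls were false. With a term for the library sets it recovered 74%, 88%, 98% and 100%, and 7.7% of its calls were false. Each simulated gene had the same spread beyond counting error in every library, which the data do not show. These shares therefore need not hold for the data, nor for genes with fewer counts. Between replicates of a genotype within the low set the squared differences were 2.04 to 2.78 times those of counting error alone (chi-square per gene), and 10.4 times in the high set for WT replicates 2 and 3. Between replicates across the sets they were 42.2 to 50.1 times. Counting error weighs most for genes with few counts. The intervals given for the near-absent genes cover counting error only.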

Results

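Total RNA was sequenced from undifferentiated H9 cells, an established human embryonic stem cell line. Of the 8 libraries, 4 came from wild-type (WT) cells and 4 from EXT1-/- cells, labelled as knockouts of the gene for the glycosyltransferase EXT1. EXT1 works with EXT2 to extend the heparan sulfate chains of proteoglycans. The deposited table held 15886 genes, each with a scaled read count per library. The deposited totals in WT replicates 1 to 4 were 37184416, 39126930, 39481430 and 37131176 scaled counts. In EXT1-/- replicates 1 to 4 they were 37288408, 37455530, 39622322 and 37432007. Values below are means with the standard deviation (SD) over the 4 libraries of a group (n = 4). Fold changes are EXT1-/- over WT on the log2 scale, with their standard error (SE). The labels do not say whether the replicates of a genotype were separate cultures, so the p-values measure spread between these libraries.

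The libraries fell into 2 sets by the share of their counts in mitochondrially encoded genes. The share was 9.98% to 10.3% in WT replicates 2 and 3 and EXT1-/- replicate 3, the high mitochondrial set. In the other 5 libraries, the low mitochondrial set, it was 5.37% to 5.58%. Between the sets 7792 genes differed with genotype as a term (limma, Benjamini-Hochberg), 3777 of them higher in the high set. The 5 libraries of the low set hold 2 WT and 3 EXT1-/- libraries, and the high set holds 2 WT and 1 EXT1-/- library. Values within each set are therefore given beside some of the results, as low and high set values.

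**Figure D1:**
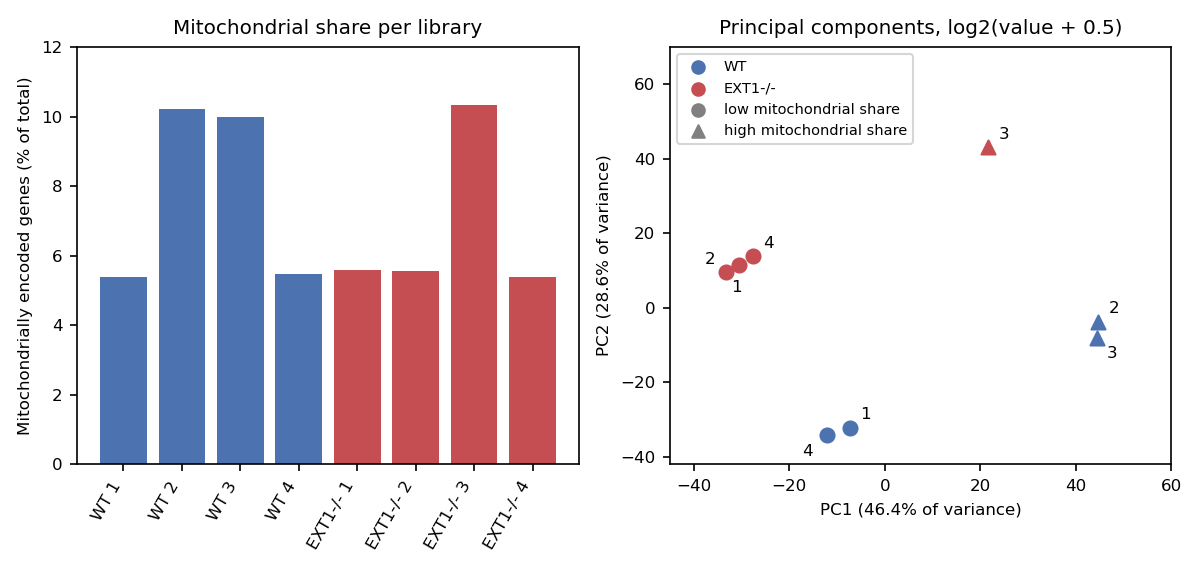
Left, percent of the scaled counts in mitochondrially encoded genes for each of the 8 libraries, with WT in blue and EXT1-/- in red. Right, the libraries on the first principal components in log2 units, numbered by replicate; PC1 (46.4% of variance) and PC2 (28.6%) together place both the genotypes and the high mitochondrial libraries (triangles) apart.

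The comparison of EXT1-/- with WT asks which transcripts differ between undifferentiated stem cells of the knockout genotype and their WT line. In EXT1-/- cells the genes that respond to FGF and ERK signalling fell together, with 16 of 24 tested members lower, among them DUSP6, which fell from 16139 ± 2034 (SD, n = 4) to 2695 ± 323 scaled counts. A fixed list of p53 target genes, here called the growth arrest and DNA damage response list, fell too. Of its 24 tested members 19 were lower, among them the cell cycle inhibitor CDKN1A. In the set test with an estimated correlation between genes the former list passed and the latter did not (adjusted p = 0.00378 and 0.0677), and with a term for the library sets as well neither passed (0.0741 and 0.0849). Genes near absence in EXT1-/- cells included PUS7L, IRAK4, ZNF726 and the catalase gene CAT. The largest rises included NPTX1, which encodes a neuronal pentraxin, and the neural transcription factor genes POU3F4 and SOX21. In all, 1182 genes were higher and 1582 lower among 15868 tested (limma with a trend, Benjamini-Hochberg adjusted p of at most 0.05), and 99 and 191 of these differed at least 2-fold.

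EXT1 (ENSG00000182197, chromosome 8, 117794490 to 118111853, minus strand, GRCh38) read 1477, 1601, 1642 and 1483 scaled counts in WT replicates 1 to 4. In EXT1-/- replicates 1 to 4 it read 757, 860, 875 and 883. The means were 1551 ± 83.4 and 844 ± 58.6 (SD, n = 4), and EXT1 fell by 0.88 on the log2 scale (SE 0.068, limma adjusted p = 8.22e-05), or by 0.83 in the low and 0.89 in the high set. The EXT1 transcript remained at 757 scaled counts or more in the EXT1-/- libraries, and its amount does not tell where the edit lies. EXT2 (ENSG00000151348, chromosome 11) read 2608 ± 423 in WT and 2569 ± 308 in EXT1-/- cells, a log2 difference of -0.02 that did not pass (adjusted p = 0.952). It passed as lower with a term for the library sets, by 0.11 on the log2 scale (adjusted p = 0.0141), as in the low set alone (0.13, adjusted p = 0.00651), and without EXT1-/- replicate 3 its log2 difference was 0.08. The heparan sulfate chain polymerases list held 5 tested genes, of which EXT1 alone passed (0 higher and 1 lower, with 0 and 1 adjusted over the list alone). Its other members EXTL1, EXTL2 and EXTL3 had log2 fold changes of -0.04, 0.08 and 0.01, each negative with a term for the library sets, and none passed in either fit. Without EXT1 the list did not pass the set test (camera adjusted p = 0.896).

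**Figure D2:**
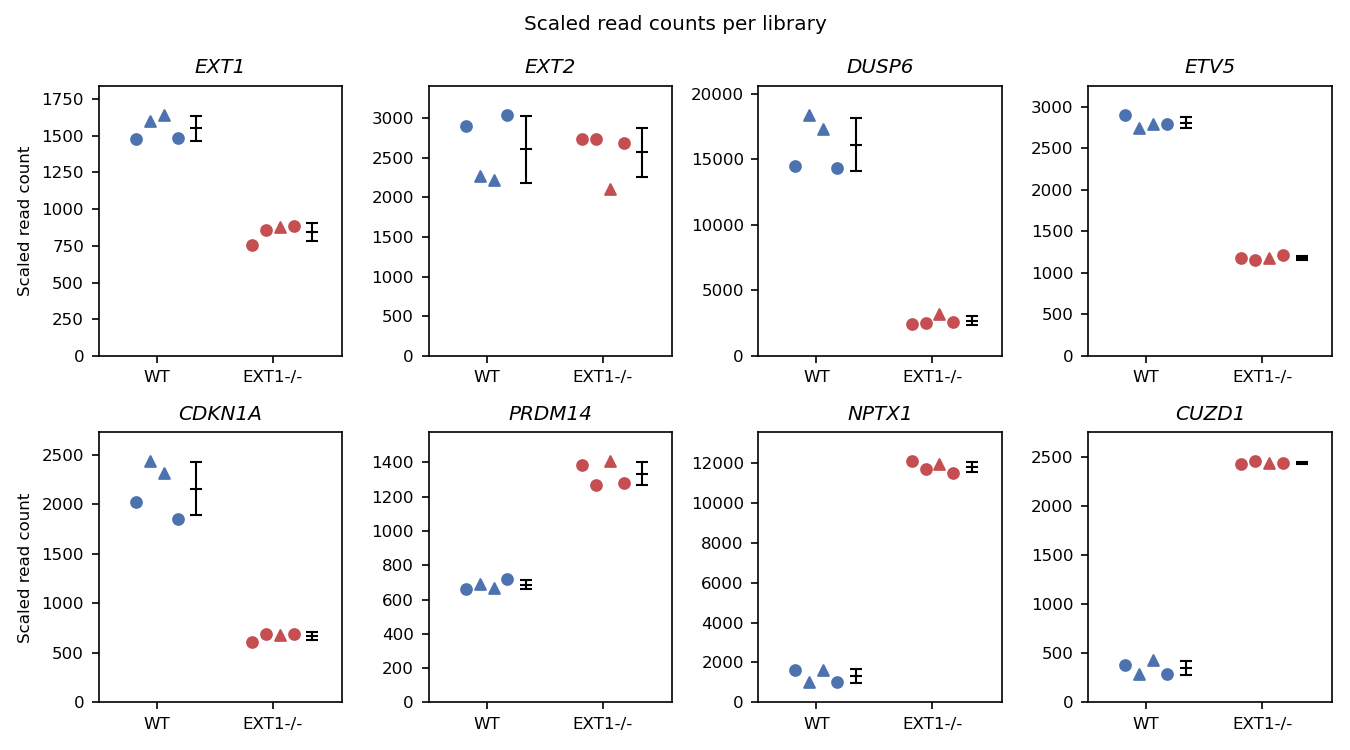
Scaled read counts of 8 genes in each library, with WT in blue, EXT1-/- in red and triangles for the high mitochondrial libraries; bars give the mean and SD (n = 4). EXT1 sits at 757 to 883 in EXT1-/- against 1477 to 1642 in WT, while the EXT2 values of the genotypes overlap.

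The 12 protein-coding genes with the largest rises had log2 fold changes from 1.96 (SOX15) to 3.21 (NPTX1). NPTX1 (ENSG00000171246, chromosome 17, 80467148 to 80477843) rose from 1311 ± 344 to 11795 ± 249.7 scaled counts, 9.24-fold (SE 0.163 on the log2 scale, limma adjusted p = 1.57e-05). CUZD1 (ENSG00000138161, chromosome 10, 122832149 to 122850793) rose from 346 ± 70.7 to 2438 ± 12.4, a log2 fold change of 2.84. POU3F4, a POU-domain transcription factor gene of the neural tube, rose from 36.8 ± 9.0 to 245 ± 17.4, and SOX21 from 58.2 ± 7.7 to 332 ± 64.8. The surface ectoderm factor GRHL3 rose by 2.27 on the log2 scale. Genes of receptors and channels in this group were ADRA2A (2.48), the serotonin receptor gene HTR1D (2.01) and the cation channel gene TRPC6 (2.15, with 2.52 in the low and 1.44 in the high set). SEMA6D, a semaphorin gene, rose by 2.06 and GADD45G by 2.02. PCDHGB5 rose by 2.13, but 58.5% of the 31-mers of its models also occur in other genes, so its reads could be assigned to more than 1 gene.

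The 12 protein-coding genes with the largest falls had log2 fold changes from -8.31 (PUS7L) to -2.46 (PDGFB, which encodes a platelet-derived growth factor chain). PUS7L (ENSG00000129317, chromosome 12, 43718993 to 43758817, minus strand) read 939 ± 92.5 in WT and 2.5 ± 0.6 in EXT1-/- cells, 0.266% of the WT mean (95% interval 0.128 to 0.490%; limma adjusted p = 7.36e-08). IRAK4 (ENSG00000198001, plus strand), a kinase gene of Toll-like and interleukin-1 receptor signalling, starts 127 bp from it and lies head to head with it. It read 157 ± 14.7 in WT and 0.5 ± 0.6 in EXT1-/- cells, 0.319% of WT (0.0385 to 1.16%). ZNF726 on chromosome 19 stood at 0.241% of WT (0.0495 to 0.705%), CAT on chromosome 11 at 1.01% (0.370 to 2.22%) and ZNF717 on chromosome 3 at 1.00% (0.271 to 2.58%). CYP4F22, a cytochrome P450 gene, stood at 1.79% of WT (0.651 to 3.93%). These intervals are exact binomial (Clopper-Pearson), cover counting error only, and are approximate because the values are scaled. The log2 fold changes of these 6 genes depend on the pseudocount. ZNF585B, CCDC152 and the homeobox gene HMX2 fell, with log2 fold changes of -4.10, -2.92 and -2.55. MCTS2P fell by 3.81, but 100% of its 31-mers occur in other genes.

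**Figure D3:**
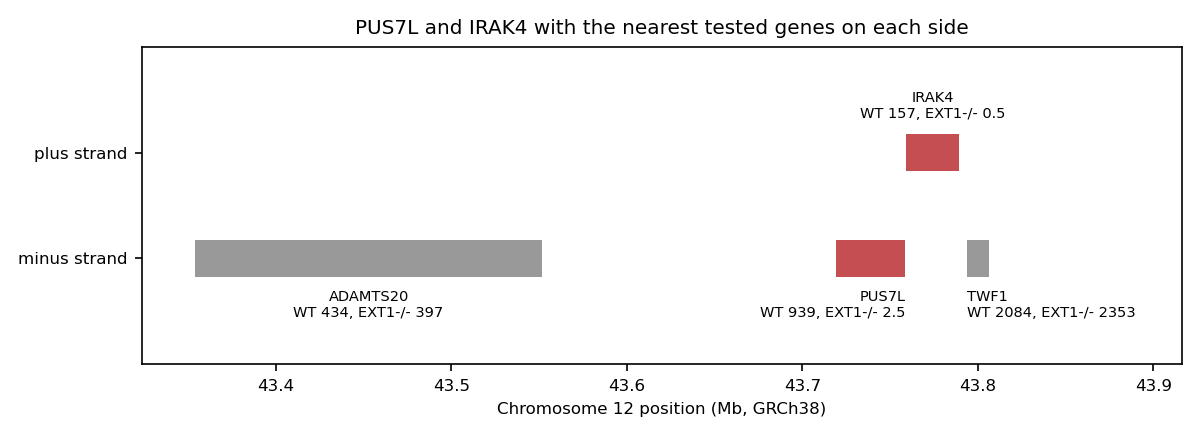
PUS7L and IRAK4 (red) and the nearest tested genes on each side (grey) on chromosome 12, with positions in Mb on GRCh38, each gene on its strand, and mean scaled counts (n = 4) as text. ADAMTS20 and TWF1 have log2 fold changes of -0.13 and 0.18, which did not pass.

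Of 24 tested genes of the FGF and ERK response list, 0 were higher and 16 lower (0 and 18 adjusted over the list alone). The set test passed (camera adjusted p = 3.29e-14, and adjusted p = 0.00378 with an estimated correlation). With a term for the library sets as well, it had adjusted p = 0.0741 with an estimated correlation and did not pass. The median log2 fold change was -0.67, with -0.74 in the low and -0.67 in the high set. DUSP6 and DUSP5, which encode phosphatases, fell by 2.58 and 1.58 on the log2 scale, with SEs of 0.107 and 0.079. ETV5, an ETS transcription factor gene, fell from 2809 ± 66.4 to 1183 ± 23.9 scaled counts (limma adjusted p = 2.6e-06). The feedback inhibitor gene SPRY2 fell from 1294 ± 26.6 to 763 ± 28.7. Among 15 tested FGF ligands and receptors, 4 were higher and 4 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.757). FGF1 rose by 1.66 and the receptor gene FGFR2 by 0.43, while FGF9 fell by 2.20 and FGF13 by 0.95. Chosen after their values were seen, FGF2 rose by 0.67 and the main receptor gene FGFR1 had a log2 fold change of -0.04 that did not pass.

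Of 24 tested p53 target genes in the growth arrest and DNA damage response list, 0 were higher and 19 lower (1 and 22 adjusted over the list alone). The counts cover this list only: GADD45G, which is not a member, rose by 2.02 on the log2 scale. The set test passed (camera adjusted p = 3.33e-14), but it had adjusted p = 0.0677 with an estimated correlation, or 0.0849 with the library set term as well. The median log2 fold change was -0.57, with -0.57 in the low and -0.65 in the high set. CDKN1A (ENSG00000124762, chromosome 6) fell from 2157 ± 265.5 to 669 ± 40.1 scaled counts (SE 0.092 on the log2 scale, limma adjusted p = 2.13e-05). BTG2, an antiproliferative gene, fell by 1.78, the secreted factor gene GDF15 by 1.87 and ZMAT3 by 1.11 on the log2 scale.

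Among 23 tested core pluripotency genes, 7 were higher and 1 lower (7 and 2 adjusted over the list alone). The list passed the set test upward (camera adjusted p = 0.0197) but had adjusted p = 0.617 with an estimated correlation, and the call ended without WT replicate 4 (0.0532) and without EXT1-/- replicate 3 (0.069). PRDM14, a transcriptional regulator of pluripotency, rose from 686 ± 26.5 to 1335 ± 69.7 scaled counts (limma adjusted p = 2.56e-05). SALL4 rose by 0.49 on the log2 scale and the noncoding RNA LNCPRESS1 by 0.63. The member that fell was NANOG, by 0.53 on the log2 scale. NANOG, SOX2 and POU5F1 were chosen after their values were seen. SOX2 rose by 0.51, and POU5F1 read 55754 ± 2403 in WT and 56311 ± 1285 in EXT1-/- cells, a difference that did not pass (adjusted p = 0.873). Of 7 tested naive pluripotency genes, 0 were higher and 2 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.865). ESRRB fell by 0.88 and TFCP2L1 by 0.30 on the log2 scale, while KLF4 (0.47) and ALPPL2 (0.98) did not pass. KLF4 passed with a term for the library sets (adjusted p = 0.0460). The log2 fold change of ALPPL2 ran from 0.604 without WT replicate 3 to 1.305 without WT replicate 1. Of 14 primed pluripotency genes, 3 were higher and 5 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.637). OTX2, a homeobox gene of the post-implantation epiblast and forebrain, rose from 818 ± 109 to 1931 ± 197 and VIM rose by 0.41, while HMX2 and DUSP6 of this list fell.

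Markers of other cell types moved both ways. Of 8 tested neuroectoderm markers, 3 were higher and 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.361). TUBB3 rose by 0.67, FEZF1 by 1.65 and DCX by 0.47 on the log2 scale, and SOX3 fell by 0.34. Of 6 neural crest markers, 0 were higher and 1 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.591). NGFR, the low-affinity nerve growth factor receptor gene, fell from 950.2 ± 136 to 222 ± 21.5. EDNRB, ERBB3 and FOXD3 had log2 fold changes of -0.40, 0.20 and 0.18, none of which passed. EDNRB (-0.49, adjusted p = 9.25e-05) and ERBB3 (0.24, adjusted p = 0.000912) passed with a term for the library sets, as they did in the low set alone and with replicate number as a block. Among 4 primitive streak and mesoderm markers, 1 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.757). The gene that rose was PDGFRA, by 0.50 on the log2 scale, and KDR fell by 0.42, while MIXL1 (-0.65) and TBX6 (-0.17) did not pass. MIXL1 stood at -0.11 without WT replicate 3, and TBX6 ran from -0.42 without EXT1-/- replicate 3 to 0.001 without WT replicate 2. Of 3 tested definitive endoderm markers, 2 were higher and 0 lower (3 and 0 adjusted over the list alone), CER1 by 0.55 and AFP by 0.65 on the log2 scale. FOXA3 had a log2 fold change of 0.19 and did not pass, but passed with a term for the library sets (adjusted p = 0.0240), in the low set alone (0.0112) and without WT replicate 2 (0.0399), and the list was too short for the set test. Of 5 trophoblast and amnion markers, 2 were higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.796). KRT7 and IGFBP3 rose by 0.55 and 0.67, and GABRP and PGF fell by 0.74 and 0.39 on the log2 scale. Among 8 mesenchyme and fibroblast markers, 2 were higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.757). VIM and COL1A1 (0.47) rose, and THY1 fell from 25236 ± 4520 to 10804 ± 2083 scaled counts, while PDGFRB fell by 0.59 on the log2 scale.

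Genes of glycosaminoglycan synthesis and of the proteins that carry the chains changed member by member, and none of their lists passed the set test. Of 17 tested genes of the glycosaminoglycan linker and precursor supply, 1 was higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.550). That gene was UGP2, which makes UDP-glucose and rose by 0.33 on the log2 scale, while PAPSS1 (-0.13), B3GALT6 (0.24) and UGDH (0.16) did not pass, but did with a term for the library sets (adjusted p = 0.0105, 0.0285 and 0.0345). Among 16 heparan sulfate modification genes, 4 were higher and 3 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.896). The extracellular sulfatase gene SULF1 fell from 1317 ± 233.5 to 632 ± 77.9, and the sulfotransferase genes NDST1, HS3ST5 and HS3ST2 rose by 0.29, 0.83 and 0.77 on the log2 scale. Of 14 chondroitin and dermatan sulfate synthesis genes, 1 was higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.438). CHPF2 rose by 0.68, and the sulfotransferase genes UST, CHST3 and CHST11 fell by 0.35, 0.38 and 0.48. Of 15 hyaluronan and keratan sulfate genes, 2 were higher and 3 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.882). TMEM2, a hyaluronidase gene also called CEMIP2, rose by 0.78 and TNFAIP6 by 1.27, while the synthase gene HAS3 fell by 0.34 and CEMIP by 0.66. Of 16 heparan sulfate proteoglycan core genes, 2 were higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.882). The glypican gene GPC4 rose from 20181 ± 942 to 28793 ± 610.5, while GPC6, SPOCK1 and GPC2 fell by 0.74, 0.42 and 0.33 on the log2 scale. Of 11 chondroitin sulfate proteoglycan core genes, 2 were higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.591). The versican gene VCAN rose from 13087 ± 799 to 19269 ± 132 and CSPG5 rose by 0.61, while BGN and PTPRZ1 fell by 1.11 and 0.15 on the log2 scale.

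Targets of other signals that bind or cross the matrix also moved both ways. Of 9 tested WNT beta-catenin response genes, 2 were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.563). AXIN2 rose from 556 ± 47.5 to 1056 ± 15.8 and PRICKLE1 by 0.80 on the log2 scale. APCDD1, whose product inhibits WNT signals, fell by 1.27 and RNF43 by 0.69, but 73.4% of the 31-mers of RNF43 also occur in other genes. Among 9 BMP response genes, 3 were higher and 4 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.757). BMP4 and ID1 rose 2.30-fold and 2.31-fold, and the inhibitory SMAD genes SMAD6 and SMAD7 fell by 0.63 and 0.59. Of 13 activin and nodal response genes, 3 were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.591). LEFTY2 rose by 0.54 and CER1 by 0.55, and SMAD7, which fell, is a member of this list too. Of 8 hedgehog response genes, 2 were higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.110). The targets PTCH1 and GLI1 rose by 0.64 and 0.61, and SMO (0.22) and CDON (-0.17) did not pass, but did with a term for the library sets (adjusted p = 0.00870 and 0.0286), and SMO also without EXT1-/- replicate 3 (0.0491). This list passed upward with a term for the library sets (0.0385), in the low set alone (0.0432) and without EXT1-/- replicate 4 (0.0414), but not with an estimated correlation (0.630, or 0.498 with the library set term as well).

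Of 33 tested basement membrane and extracellular matrix genes, 4 were higher and 9 lower (5 and 10 adjusted over the list alone; camera adjusted p = 0.438). COL7A1 rose from 130 ± 22.5 to 450.5 ± 30.4 and COL12A1 by 1.07 on the log2 scale, while FBN2 and LAMB1 fell by 0.67 and 0.58. Among 20 integrin and focal adhesion genes, 1 was higher and 5 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.376). This list passed downward in the low set alone (0.0493), but not with an estimated correlation over the 8 libraries (0.630, or 0.498 with the library set term as well). ITGB1 fell from 28637 ± 2075 to 22108 ± 423, ITGA5 by 0.40 and the focal adhesion kinase gene PTK2 by 0.21 on the log2 scale, and CAV1 rose by 0.35. Of 14 YAP and TEAD response genes, 0 were higher and 5 lower (0 and 5 adjusted over the list alone). The list passed downward (camera adjusted p = 0.0493) but had adjusted p = 0.358 with an estimated correlation. It did not pass without WT replicate 1 (0.0973), WT replicate 4 (0.0866), EXT1-/- replicate 1 (0.0575) or EXT1-/- replicate 3 (0.095), nor with replicate number as a block (0.0777). CTGF fell from 6035 ± 351 to 3325 ± 89.6, and AMOTL1, TEAD1 and AMOTL2 fell by 0.64, 0.42 and 0.44 on the log2 scale.

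Among 19 tested hypoxia and glycolysis genes, 1 was higher and 9 lower (1 and 11 adjusted over the list alone). The list passed downward (camera adjusted p = 0.00112) but had adjusted p = 0.630 with an estimated correlation. The glucose transporter genes SLC2A1 and SLC2A3 fell by 0.74 and 0.60 on the log2 scale, and SLC2A1 went from 13061 ± 633 to 7800.2 ± 359. P4HA2 fell by 0.52, and EGLN3, a prolyl hydroxylase gene that HIF induces, rose 1.51-fold. Of 23 cholesterol synthesis genes, 4 were higher and 0 lower (4 and 0 adjusted over the list alone). This list passed upward (camera adjusted p = 0.0390), had adjusted p = 0.630 with an estimated correlation, and did not pass without WT replicate 3 (0.0858). LSS and MVK rose by 0.30 and 0.29 on the log2 scale. Of 24 unfolded protein and integrated stress response genes, 1 was higher and 4 lower (1 and 5 adjusted over the list alone). The list did not pass (camera adjusted p = 0.361), but passed downward with a term for the library sets (0.0385) and in the low set alone (0.0193). With an estimated correlation it did not pass (0.733, or 0.199 with the library set term as well). SESN2, ATF3, PHGDH and ASNS fell by 0.43, 0.38, 0.23 and 0.49 on the log2 scale. Among 20 cell cycle G2M genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.492). The mitotic checkpoint gene BUB1 rose by 0.35, KIF23 by 0.17 and CDC20 by 0.17, and BUB1B fell by 0.19. Of 12 interferon response genes, 1 was higher and 2 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.591). MX1 rose from 141 ± 12.6 to 266 ± 10.7, BST2 and IFITM1 fell by 0.75 and 0.46, and IFITM2 had a log2 fold change of -0.80 that did not pass. IFITM2 passed with a term for the library sets (-0.61, adjusted p = 3.22e-06), as in the low set alone, with replicate number as a block, and without WT replicate 1 (0.0458) or EXT1-/- replicate 3 (0.0127).

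Of 20 tested imprinted genes, 2 were higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.563). PEG3 and NAP1L5 rose by 0.48 and 0.53 on the log2 scale, while KCNQ1OT1 (-0.53) and MAGEL2 (0.18) did not pass, but did with a term for the library sets (adjusted p = 0.0280 and 0.0466). KCNQ1OT1 is an antisense RNA, and the strand setting of the authors' counting is not stated, so its value could include reads of the gene it overlaps. Of 17 genes of the 20q11.21 stem cell amplicon, a region often gained in cultured stem cells, 1 was higher and 3 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.361). ID1 rose, and XKR7, NOL4L and POFUT1 fell by 0.44, 0.45 and 0.21 on the log2 scale. Of 23 protocadherin cluster genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.361). PCDHB16 rose by 0.56 and PCDHAC2 fell by 0.53, while PCDHA6 and PCDHA1 rose by 0.85 and 1.03, with 64.3% and 64.9% of their 31-mers also in other genes. The 3 tested replication-dependent histone genes were higher (3 and 0 adjusted over the list alone), HIST1H2AC by 1.11, HIST1H1C by 0.71 and HIST1H2AG by 0.56 on the log2 scale (0.81 in the low and 0.17 in the high set). Of 13 mitochondrially encoded genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, and 0 at an unadjusted p under 0.05; camera adjusted p = 0.591). MT-ND2, MT-ND3, MT-ND4 and MT-ND5 had log2 fold changes of -0.23, -0.21, -0.28 and -0.25, and 56.9% of the 31-mers of MT-ND2 also occur in other genes. With a term for the library sets this list turned upward (0.0264), as in the low set alone (0.00951), but with an estimated correlation as well it did not pass (0.498). With the library set term the log2 fold changes of these 4 genes were 0.033, -0.004, 0.007 and 0.005 and did not pass, while 6 of the 13 members were called higher, as were 6 in the low set alone.

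**Figure D4:**
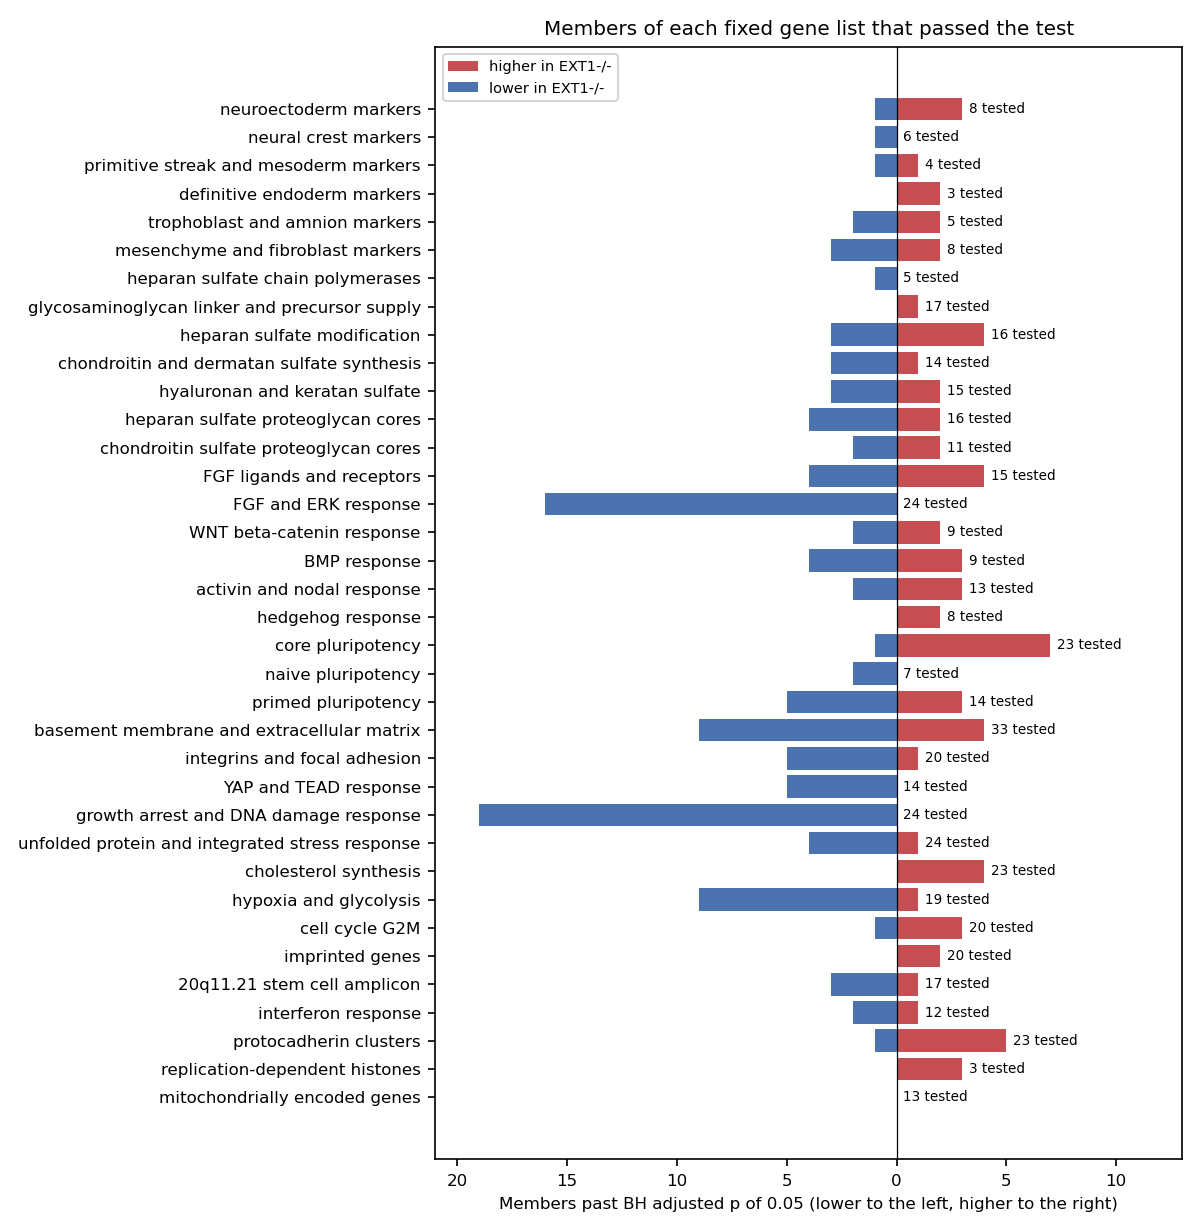
For each fixed list, the number of tested members that passed the test (limma, Benjamini-Hochberg), with members lower in EXT1-/- drawn to the left in blue and higher to the right in red. The growth arrest and DNA damage response list (19 lower) and the FGF and ERK response list (16 lower) have the longest bars.

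Of the 22 autosomes, 0 passed the set test (camera adjusted p = 0.986 for each, and the lowest unadjusted p was 0.145). With a term for the library sets 3072 genes were higher and 3166 lower in EXT1-/- cells, and these included the 2764 genes called without it, each with the same sign. In the low set alone 3242 were higher and 3246 lower, with 2677 of the 2764 among them. Without EXT1-/- replicate 1, 2 or 4 the number of higher genes fell to 715, 728 or 702. The groups did not overlap in 3790 genes, 23.9% of those tested, where chance gives 2.86%. For the called genes named by the rule, except NAP1L5 and PCDHA1, the 4 EXT1-/- values lay wholly above or below the 4 WT values. The rule required this of the genes with the largest changes. It named list genes by their smallest adjusted p, which favours groups that do not overlap. The lack of overlap in named genes is therefore no separate evidence for their calls. Each called named gene kept its sign within both library sets, which the lack of overlap fixes in advance for all but NAP1L5 and PCDHA1. In 18 of the 136 called genes named by the rule the low and high set values differed by over 1.5 times. Among them were, low set first, SOX3 (-0.48 and -0.17), AFP (0.85 and 0.49), PGF (-0.51 and -0.26), COL1A1 (0.41 and 0.67), HAS3 (-0.41 and -0.26), CSPG5 (0.53 and 0.86), RNF43 (-0.45 and -0.98), ESRRB (-1.04 and -0.46), TEAD1 (-0.37 and -0.56), LSS (0.24 and 0.41), BUB1B (-0.15 and -0.23), KIF23 (0.14 and 0.21), CDC20 (0.12 and 0.22), NAP1L5 (0.57 and 0.30) and NOL4L (-0.45 and -0.28). These differences between the sets were not tested. The calls of 17 named genes, among them AFP, ASNS, BUB1B, CDC20, CHST11, GPC2, HIST1H2AG, KIF23, MVK, NAP1L5, PCDHA1, PCDHAC2, PGF, POFUT1, PTPRZ1 and SOX3, ended without at least 1 of the libraries, with adjusted p-values then between 0.0508 (PGF) and 0.144 (CDC20, without EXT1-/- replicate 4). The authors' deposited comparison called 796 genes up and 1190 down, of which 1864 were among the 2764 called here. Across genes, which are not independent replicates, the fold changes of the authors and those computed here had a correlation of 0.972. The median and the mean log2 fold change had opposite signs for the hyaluronan and keratan sulfate, heparan sulfate proteoglycan core, WNT, BMP, naive pluripotency, trophoblast and mesenchyme lists. Lists with a count of 0 in a direction had 1 member in it at an unadjusted limma p under 0.05 for the neural crest, naive, YAP, growth arrest, linker, hedgehog and imprinted lists. They had 0 for the polymerase, FGF and ERK response, endoderm, cholesterol and histone lists.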

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

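Chosen after the results were seen were the tests of displacement by mitochondrial reads and of shared sequence in the genes that share it. The count of genes in other splits of the libraries was planned before. The share of splits that would decide it, and its version with the library set term, were chosen after. The tests of GC content with length and of genes with little shared sequence were written before. Each group of 4 values behind the results (326 groups) was searched for a library whose gap to its nearest neighbour exceeded the share of their range that Dixon's 95% critical value sets. In 33 groups there was such a library, where chance gives about 1 in 20 groups, and in 23 of the 33 it was EXT1-/- replicate 3. That library is the 1 high mitochondrial library of its genotype, so a gene that differs between the library sets tends to flag it. WT has 2 libraries in each set, so such a gene tends not to flag a WT library. The groups share the same 8 libraries and are not independent.

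In EXT1-/- replicate 3, the deposited total was 39622322 scaled counts against 37288408 to 37455530 in the other EXT1-/- libraries, and its mitochondrial share was 10.326% against 5.384% to 5.576%. MT-ND2, MT-ND3, MT-ND4 and MT-ND5 read 215400, 32431, 483920 and 192040 there. The highest values of the other EXT1-/- libraries were 104953, 19005, 222166 and 98839. Among heparan sulfate genes in that library, EXT2 read 2108 (others 2691 to 2741), EXTL2 read 1829 (2779 to 2856) and GPC6 read 2178 (1912 to 1940). Among chondroitin sulfate genes, CHPF2 read 653 (736 to 745), CHST11 read 652 (502 to 514) and BGN read 231 (151 to 157). Among signalling genes, DUSP6 read 3174 (2471 to 2589), APCDD1 read 123 (91 to 95), GLI1 read 655 (508 to 518) and POFUT1 read 2343 (2099 to 2140). Among surface and matrix genes, THY1 read 13926 (9675 to 9862), COL7A1 read 405 (464 to 467), PCDHB16 read 299 (260 to 266) and IFITM2 read 6744 (3878 to 4000). EDNRB read 391 there (486 to 501), TBX6 read 108 (52 to 54) and ASNS read 5359 (7058 to 7370).

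In other EXT1-/- libraries, replicate 1 had 609 scaled counts of CDKN1A (others 685 to 692), 2236 of PRICKLE1 (2353 to 2375) and 796 of PDGFRB (846 to 849). Replicate 4 had 14 of HMX2 (21 to 22) and 244 of MAGEL2 (others up to 257). In WT replicate 2, PUS7L read 801 (others 975 to 993) and IRAK4 read 135 (162 to 167). In WT replicate 3, ITGB1 read 31735 (27425 to 27887) and the mesendoderm gene MIXL1 read 180 (31 to 54). ZNF717 read 92 in WT replicate 4 (102 to 103).

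The set of 3 libraries with a high mitochondrial share crosses the genotypes, and 7792 genes differ between the sets. GC content and length of transcripts explained 4.95% of the variance of the set difference across genes, which argues against them as the whole source. Displacement by mitochondrial reads would change each nuclear gene by the same factor. The median set difference of nuclear genes was -0.0018 on the log2 scale in these scaled values, so taking it off changed little. After it was taken off, 49.1% of the nuclear genes differed between the sets, which argues against displacement as the whole source too. Read assignment between similar gene models does not account for the genes with little shared sequence, of which 47.5% differed. For genes that share sequence it stays open: their set differences were 1.18 times those of other genes relative to their spread, and they made up 72.6% of the 372 differences over 1 on the log2 scale against 8.9% of the genes tested. Of 34 gene lists and marker sets tested between the sets, 1 passed, the mitochondrially encoded genes (camera adjusted p = 9.01e-16, or 0.196 with an estimated correlation), which follows from how the sets were defined. The labels name neither a batch nor a biological group that follows the sets, so a biological source stays open. Both sets hold both genotypes, so genotype differences were also computed within each.

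The count of genes called between the genotypes was 2764, and of the 35 splits of the 8 libraries into 4 and 4 only the real split gave a count as large (1 of 35). The highest other split gave 4, but each other split mixes the genotypes, so a genotype difference adds to its spread and lowers its count. With 35 splits the smallest share possible is 1 of 35, so this comparison cannot exclude chance. With the term for the library sets the real split gave 6238 and the highest other 2.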

How the results depend on the processing

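The term for the library sets (alone or with an estimated correlation), the low mitochondrial set alone and the treat test were chosen after seeing the data, and the other alternatives before. DESeq2, the edgeR likelihood ratio test, voom and glmTreat were not run, because they need raw counts. The counts of genes higher and lower in EXT1-/- cells (1182 and 1582) stayed within 1.5 times under RLE scaling, no filter, 1 CPM, both pseudocounts and the replicate block (1054 and 1491, of which 2259 genes were shared). They moved with the term for the library sets (3072 and 3166), in the low mitochondrial libraries alone (3242 and 3246), at an adjusted p under 0.01 (518 and 813) and with limma treat against a fold of 1.2 (202 and 395). A stricter test lowers a count by construction. For the library sets the residual SD fell from a median of 0.147 to 0.0811 on the log2 scale. With a library left out the higher count ran from 702 (without EXT1-/- replicate 4) to 1364 (without EXT1-/- replicate 3), with 715 and 728 without EXT1-/- replicates 1 and 2, and the lower count from 1066 to 1754. Counts at least 2-fold higher ran from 74 to 112 and lower from 162 to 220 over all alternatives. The EXT1 log2 fold change stayed between -0.90 and -0.83 in every alternative run. The replicate numbers were used as a block only as an alternative, and the values gave no sign that they pair the samples. Correlations of same-numbered libraries were 0.342, -0.517, 0.504 and 0.323 for replicates 1 to 4. The libraries of replicates 1, 3 and 4 share a library set and those of replicate 2 do not, so these values do not show pairing. EXT1-/- replicates 1 to 4 correlated most with WT replicates 4, 4, 2 and 1, none with the same number.

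The number of lists past the set test (6) ran from 4 to 7 with a library left out, was 5 with the replicate block or RLE and 9 with the library set term, and moved to 10 in the low mitochondrial libraries, 1 with an estimated correlation and 18 with fry. With an estimated correlation the growth arrest (0.0677), core pluripotency (0.617), YAP (0.358), cholesterol (0.63) and hypoxia (0.63) calls ended, while the FGF and ERK list kept its call. With an estimated correlation and the library set term together, 0 lists passed: FGF and ERK (0.0741), growth arrest (0.0849), core pluripotency, YAP and cholesterol (each 0.199) and hypoxia (0.498). Over the other alternatives the FGF and ERK list stayed past the threshold. YAP also lost its call with RLE scaling (0.0517) and the replicate block (0.0777). With fry these lists passed: chondroitin synthesis, primed pluripotency and imprinted genes (each 0.00633), chondroitin cores (0.00394), WNT (0.0106), hedgehog (0.0339), basement membrane (0.000363) and integrins (0.00441). So did the markers of neuroectoderm (0.00268), neural crest (0.0218), trophoblast (0.0409) and mesenchyme (0.00267). With the library set term, and in the low mitochondrial libraries, hedgehog (0.0385, 0.0432) and the stress response (0.0385, 0.0193) passed, integrins passed in the latter (0.0493), and the mitochondrial list turned upward (0.0264, 0.00951). With the library set term and an estimated correlation these 4 lists did not pass (0.199 for the stress response and 0.498 for the others). With a library left out, p ran from 0.0414 (without EXT1-/- replicate 4) to 0.276 for hedgehog and from 0.00845 to 0.069 for core pluripotency, which ended without WT replicate 4 (0.0532) and EXT1-/- replicate 3. It ran from 0.0265 to 0.0973 for YAP and from 0.0258 to 0.0858 (without WT replicate 3) for cholesterol. YAP ended without WT replicates 1 and 4 (0.0866) and EXT1-/- replicates 1 (0.0575) and 3 (0.095). The cause was not tested for these lists. Over the alternatives that keep all libraries or drop the high set, adjusted p ran from 5.14e-16 to 0.0741 for FGF and ERK, from 1.27e-16 to 0.0849 for growth arrest, from 0.00164 to 0.617 for core pluripotency, from 0.000363 to 0.358 for YAP and from 0.0339 to 0.63 for hedgehog. It ran from 0.0235 to 0.63 for cholesterol and from 0.00106 to 0.63 for hypoxia. Of 22 autosomes, 0 passed in every alternative run.

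Of 159 named genes besides EXT1, 135 passed, and 0 of the 135 reversed in any alternative. Where the groups do not overlap, a left-out library, the replicate block or the library set term cannot reverse a sign. The lack of reversals there is no separate evidence. With a library left out, 17 of the 135 lost their call at least once, and 5 did so with the replicate block (AFP, CDC20, HIST1H2AG, KIF23 and PTPRZ1). PCDHAC2 lost it without EXT1-/- replicate 4 alone (0.0542) and ASNS without WT replicate 1 (0.0564) or 4 (0.0571), while the other 15 lost it without 3 to 8 of the libraries each. Of the 24 that did not pass, 13 passed in at least 1 alternative: 13 with the library set term, 8 in the low mitochondrial libraries, 4 with the replicate block and 1 with RLE scaling. With a library left out, IFITM2 passed without WT replicate 1 (0.0458) and EXT1-/- replicate 3 (0.0127), FOXA3 without WT replicate 2 (0.0399) and SMO without EXT1-/- replicate 3 (0.0491). In 9 of the 24 the sign changed in at least 1 alternative, without a pass on the other side, as for MT-ND2 (-0.23, or 0.03 with the library set term) and EXT2 (-0.02, or 0.08 without EXT1-/- replicate 3). Depth limits the near-absent genes, whose EXT1-/- sums were 1 to 19 scaled counts.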

Other observations

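Chosen after the results were seen were the genes of this paragraph and the groups of the next. So were the tests of a shared promoter, of a loss that spans PUS7L and IRAK4, and of the library sets for the lists. The tests of neighbouring genes, of near-identical copies, and of GC content with length for the lists were written before, and what the first of these covers was narrowed after. Several transcription factor genes outside the rule for named genes changed in EXT1-/- cells. IRX2, an Iroquois homeobox gene, rose from 212 ± 14.3 to 695.5 ± 89.3 scaled counts (SD, n = 4; limma adjusted p = 2.13e-05), and the forkhead gene FOXB1 rose from 44.5 ± 32.6 to 98.5 ± 19 with overlapping groups (adjusted p = 0.0452). GBX2, a homeobox gene of the midbrain and hindbrain border, fell from 51 ± 21.2 to 9.0 ± 3.4, and ONECUT1 fell from 116 ± 21.1 to 24.8 ± 6.7. POU3F1 fell from 312 ± 64.8 to 128.5 ± 37.5 and EMX1, a homeobox gene of the forebrain, from 441 ± 61.5 to 193 ± 39.2.

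Of 47 tested proteasome subunit genes, 4 were higher and 0 lower (8 and 0 at an unadjusted limma p under 0.05). The group passed the set test upward (camera adjusted p = 0.00705) but had adjusted p = 0.650 with an estimated correlation. With the library set term 15 were higher and 3 lower. The groups of this paragraph were picked after their values were seen, and their set tests were adjusted over these groups alone. Their adjusted p-values are therefore no separate evidence of a change. Of 465 tested genes with ZNF symbols, zinc finger genes for the most part, 43 were higher and 47 lower (camera adjusted p = 0.367), with 18 of the higher and 23 of the lower on chromosome 19. The higher and lower counts of this group were 108 and 91 with the library set term. At an unadjusted limma p under 0.05 they were 92 and 69. Of 76 cytosolic ribosomal protein genes, 0 were higher and 0 lower (limma; 0 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.481). With the library set term 2 were higher and 16 lower, and the group passed the set test (adjusted p = 0.0112) but not with an estimated correlation as well (0.53).

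In 12 genes on 8 chromosomes the EXT1-/- mean lay under 1/20 of the WT mean, among them PUS7L, IRAK4, ZNF726, CAT, ZNF717, CYP4F22 and C9orf64, and the 22 nearest tested genes, PUS7L and IRAK4 among them, had a median log2 fold change of -0.143. These neighbours lay at a median distance of 104679 bp, and 7 of them within 20 kb. The median change argues against losses that reach these neighbours for the genes as a group, and says nothing of shorter losses, which stay open. Nor does it exclude a loss that reaches a neighbour for single genes, since 7 of the 22 neighbours (PUS7L, IRAK4, ZNF100, RASAL3, ROBO2, ABTB2 and KIF27) were lower. Reads lost to a near-identical copy are argued against by a median of 4.7% of 31-mers shared with another gene. For PUS7L and IRAK4 a change at a shared promoter and a loss that spans both genes cannot be told apart, since each is near absence (IRAK4 at -7.499 and PUS7L at -8.31 on the log2 scale), this is the only such pair, and 0.274% of their WT counts is left, too few to show whether the genes are still read. For the others no biological explanation was tested, and the labels do not name the number of clones.

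The lower FGF and ERK response and growth arrest and DNA damage response lists had negative medians in both library sets, where the median nearest 0 was -0.569, and after removal of the trend with GC content and length, where it was -0.541. That trend was weak: it explained 0.33% of the variance of the fold changes across genes, and its own median was -0.036 and -0.024 over the lists, with -0.232 for the lowest gene. These are medians and not calls: in the set test with an estimated correlation and the library set term neither list passed (adjusted p = 0.0741 and 0.0849), nor the latter without that term (0.0677), and the high set holds 1 EXT1-/- library. The medians within the sets argue against the sets as the whole of either fall, and the size of the trend against GC content and length. A candidate explanation for the FGF and ERK list is reduced FGF signalling where heparan sulfate is short, since FGF receptors use it as a coreceptor. It stays an untested hypothesis, because neither heparan sulfate nor protein activity was measured, and a difference between clones stays open for both lists.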
